A study of Mus musculus with 7 samples.

How the data were processed

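The series holds 7 RNA sequencing libraries from cultured mouse retinas homozygous for the orJ allele of Vsx2, taken from E12.5 embryos and cultured for 1 day. The treatment field of the labels gave the group of each library, 4 treated with DBZ and 3 with vehicle, and the sample titles gave the replicate numbers. Per the labels' protocols, RNA was extracted with Trizol, polyadenylated RNA was selected, and libraries were made with a kit that keeps strand information. The deposited files hold raw read counts per gene, whole numbers that are not normalised, 1 file per library. Per the submitters' processing notes, the tools were bcl2fastq, FastQC, Trim Galore, STAR and HTSeq, with the mouse genome build mm10 (GRCm38). Their versions, their settings, the strand setting of the counting and the annotation release are not given in the sources used here. Because the strand setting is not known, counts of genes that overlap on opposite strands are uncertain. Counts of near-identical copies such as Hspa1a and Hspa1b are uncertain too, because their reads cannot be fully told apart.

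Each deposited count file lists 53715 gene identifiers and 5 summary lines of reads not assigned to a gene. Identifiers were matched without their version number to the GENCODE M21 annotation of GRCm38, which gave symbols and coordinates for 53620 of them; 51464 also carried the same version, and 95 were left without a symbol. Where 2 identifiers shared a symbol, the identifier with more counts was used. The summary lines stayed out of library sizes and tests. Reads in no feature made up 11.5% to 14.6% of the lines' sum, ambiguous reads 5.14% to 5.93% and reads that did not map uniquely 4.82% to 5.75%. Counts assigned to genes ran from 23071848 (vehicle replicate 1) to 55171524 (DBZ replicate 1). No pair of libraries agreed within sampling noise (chi-square per gene of 27.9 or more), so all 7 were used as separate replicates. The libraries carry no unique molecular identifiers, so counting intervals cover counting error only.

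Genes were tested with edgeR 4.0.16 in R 4.3.3. Low counts were removed with filterByExpr (minimum count 10, minimum total 15), which left 20099 genes of 31067 with any count. Libraries were scaled by TMM, dispersions were estimated with estimateDisp, and DBZ was compared with vehicle by the quasi-likelihood F test with robust estimation (glmQLFit and glmQLFTest, two-sided), with no covariate. P-values were adjusted by the Benjamini-Hochberg method, and genes below 0.05 were called. The common biological coefficient of variation was 0.279. The standard error of a log2 fold change was taken as its size divided by the square root of F, which is approximate. Normalised CPM are counts expressed relative to the TMM-scaled library size.

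The median log2 fold change of all tested genes was 0.01. It stayed below 0.1 under the other scalings tried. A total of 28 lists of pathway genes and cell type markers, including markers of lens, pigment epithelium, mesenchyme, endothelium, blood, microglia, neural crest and surface ectoderm, was written before the data were examined. Lists with 3 or more tested members were compared with all other genes by camera (limma 3.58.1) with a preset correlation of 0.01, adjusted over the 28 lists. The test was repeated with a correlation estimated from the data, and fry was run beside it. Counts of called members are given over all genes and adjusted over the list alone. The share of counts from lens markers, erythroid genes and other groups was compared by an exact permutation test on the absolute difference of means over all 35 splits of the 7 libraries.

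Genes were named by a rule fixed at the same time as the lists. It takes the 8 largest rises and 8 largest falls among called genes whose groups do not overlap and whose mean is at least 5 CPM, the 5 smallest p-values in each direction, up to 4 members of each list by p-value (all members where 5 or fewer were tested or called) and a fixed panel of genes of retinal development. Heyl was named from outside the rule after its values were seen. Of the genes in the text that were followed through all alternative settings, 89 came from the rule and 10, Heyl among them, were chosen after their values were seen.

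The steps were tested on simulated counts drawn from the means and library sizes of these libraries, with seeded changes in 200 genes among 19353 in the comparison of DBZ with vehicle. Of seeded changes, 22.4% were recovered at a log2 change of 0.5, 64.2% at 1 and 89.4% at 2, with 5 false calls among 122. With no change seeded, 1 gene and 0 lists were called. Changes were seeded only in genes with a mean of at least 1 CPM, and genes were drawn independently of each other. The simulation therefore does not show how often the preset correlation calls lists whose members vary together.

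Alternatives were size factors (RLE) or library size alone in place of TMM, no filter and a stricter filter on low counts (mean of at least 10 CPM), DESeq2 1.42.0, limma-voom, robust estimation switched off, lens markers removed or used as a covariate, the replicate number as a block, a test against a log2 change of 0.5 (glmTreat) and leaving out each library in turn. Alternatives added after the data were seen were thinning all libraries to the smallest total, removing trends of GC content and length per library, leaving out DBZ replicate 3 and vehicle replicate 3 together, and a test of mouse Reactome gene sets of 10 to 300 tested genes (fgsea 1.28.0 package data). Figures were drawn with matplotlib.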

Results

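Gene expression was measured by RNA sequencing in retinas taken from E12.5 embryos of mice homozygous for orJ (ocular retardation J), an allele of Vsx2. Vsx2 encodes a homeodomain transcription factor of retinal progenitor cells, and the orJ allele carries a premature stop codon in its coding sequence. Retinas with the lens attached were kept in culture for 24 h with 300 nM dibenzazepine (DBZ) in 0.1% DMSO or with 0.1% DMSO alone as the vehicle, and EdU at 10 µM was present for the last 30 min. DBZ inhibits gamma-secretase, the membrane protease complex that releases the intracellular domain of cleaved Notch receptors. The comparison asked how blocking this protease alters the transcriptome of the mutant retina. Libraries of polyadenylated RNA were available from 4 DBZ cultures and 3 vehicle cultures, described as biological replicates in the series design. Counts assigned to genes totalled 55171524, 42671205, 37810244 and 43403709 in DBZ replicates 1 to 4. They totalled 23071848, 49026680 and 45947321 in vehicle replicates 1 to 3, so vehicle replicate 1 was the shallowest library. Every culture was mutant, and no wild-type retina was analysed here.

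Transcripts of the mutated gene were abundant in all 7 libraries. Vsx2 (ENSMUSG00000021239.12, chromosome 12, 84569762 to 84595457, GRCm38) measured 608, 637, 589 and 433 normalised CPM (counts scaled by library size) in DBZ replicates 1 to 4, against 649, 717 and 649 in vehicle replicates 1 to 3. The group means were 567 ± 91.6 CPM (SD, n = 4) with DBZ and 672 ± 39.1 CPM (SD, n = 3) with vehicle, and the difference did not pass the test (edgeR adjusted p = 0.44). Gene counts do not show the orJ base change, so these levels do not check the genotype.

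DBZ changed 386 of 20099 tested genes, of which 318 were lower and 68 were higher. The genes that fell were led by the machinery of DNA replication and mitosis, and Top2a, Uhrf1, Cenpe, Kif2c and Cdca2 had the smallest p-values of all. Top2a, the topoisomerase that untangles replicated chromosomes (ENSMUSG00000020914.17, chromosome 11, 98992943 to 99024189), fell from 398 ± 1.79 to 187 ± 9.77 CPM (SD, n = 3 and n = 4), a 2.13-fold drop. Most changes were modest: 33 genes were lower and 15 higher by at least 2-fold. In all 386 genes the DBZ libraries lay entirely above or entirely below the vehicle libraries. Such separation held for 14.1% of the tested genes and would hold for 5.71% by chance. Calls with 4 and 3 libraries all but require it, so it is no separate support for them. The count depended on single libraries, with 179 genes without DBZ replicate 1, 769 without DBZ replicate 2, 183 without vehicle replicate 1, 210 without vehicle replicate 2 and 168 without vehicle replicate 3. Higher genes were the less stable part, with 11 without DBZ replicate 1 and 299 without DBZ replicate 2, and 2 of the 35 splits of the libraries gave 68 or more. Lower genes made up 82.4% of the calls here, 93.9% without DBZ replicate 1, 61.1% without DBZ replicate 2 and 62.2% of 882 calls made with DESeq2, and 684 genes were called when no filter on low counts was used.

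Cell cycle transcripts fell as a group in the DBZ retinas. All 19 mitotic (G2/M) genes tested were called as lower, with a median log2 fold change of -0.92. All 19 DNA replication (G1/S) genes had lower fitted means, with a median of -0.62, and 16 of them were called over all genes. Adjusted over the list alone, all 19 genes of each list were lower. Mki67, which marks cycling cells, fell 2.02-fold, from 441 ± 16.2 to 218 ± 42.7 CPM (SD). Ccna2, the cyclin of S phase and G2, had a log2 fold change of -0.93 ± 0.08 (SE), and Kif11, a spindle motor, had one of -1.01 ± 0.09. Among the replication genes, Uhrf1, which maintains DNA methylation behind the replication fork, fell 2.14-fold (log2 fold change -1.10 ± 0.08), and Rrm2, a subunit of ribonucleotide reductase, fell 2.02-fold. E2f1, a transcription factor driving S phase entry, fell 1.81-fold, and Mcm5, part of the replicative helicase, fell 1.53-fold. The list tests gave adjusted p = 9.6e-92 for the mitotic genes and 7.7e-44 for the replication genes (camera, preset correlation of 0.01), and adjusted p = 0.017 and 0.024 with an estimated correlation. Each of these 7 named genes stayed called whichever library was left out.

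**Figure D1:**
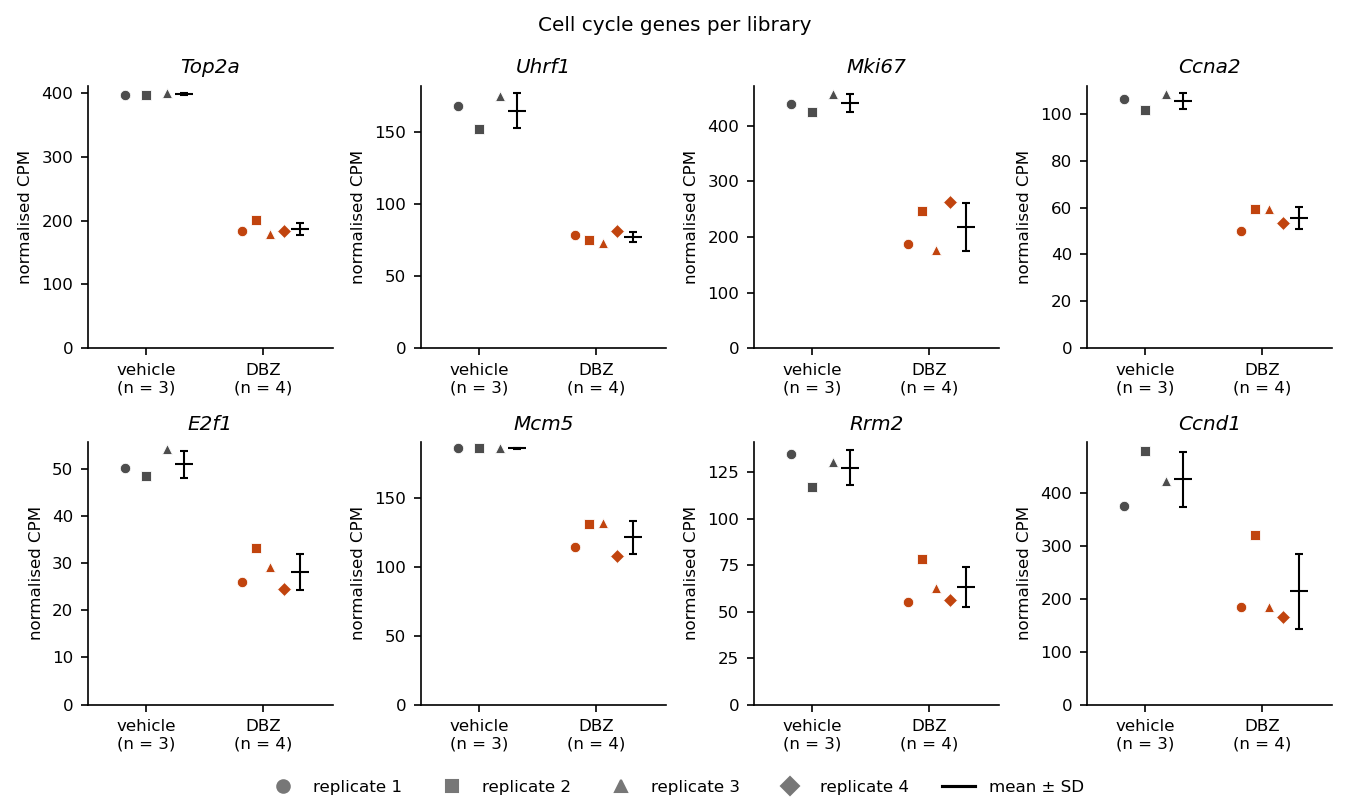
Normalised CPM of 8 cell cycle genes in each library (symbols, replicate numbers as in the key), with the mean and SD of the 3 vehicle and 4 DBZ libraries beside them. All DBZ libraries lie below all vehicle libraries in each of the 8 panels, although Ccnd1, at 320 CPM in DBZ replicate 2, did not pass the test over all genes.

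None of the 9 tested cell cycle exit genes was called as higher. Rbl1, an E2F-binding member of the retinoblastoma family, was the only one called, and it was lower (log2 fold change -0.51 ± 0.09 (SE), edgeR adjusted p = 0.019). Adjusted over the list alone, Rbl1 and Cdkn2c were lower. Cdkn1c, the cyclin-dependent kinase inhibitor p57, measured 254 ± 29.9 CPM (SD, n = 4) with DBZ and 300 ± 9.65 CPM (SD, n = 3) with vehicle, with adjusted p = 0.29. The list passed the test in the downward direction (adjusted p = 0.011) but not with an estimated correlation (adjusted p = 0.28), and leaving out vehicle replicate 3 ended its call (adjusted p = 0.075), as did the stricter filter on low counts (0.18) and leaving out DBZ replicate 3 with vehicle replicate 3 (0.080). The call of Rbl1 ended without DBZ replicate 1 (adjusted p = 0.079) and without vehicle replicates 1, 2 and 3 (adjusted p = 0.10, 0.10 and 0.067).

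Notch target genes were lower with DBZ as a list. Of 15 tested Notch target genes 14 had lower fitted means, but only Dtx4, a Notch pathway E3 ubiquitin ligase (chromosome 19, 12466338 to 12501454), passed over all genes. Dtx4 fell from 184 ± 8.41 to 121 ± 3.14 CPM (SD), a 1.52-fold drop with edgeR adjusted p = 0.00093. The count adjusted over the list alone was 6 lower and none higher. These were Dtx4, Hey1, Notch3, Nrarp, Hes1 and Heyl. Hey1, a Notch effector, had a log2 fold change of -0.81 ± 0.19 (SE) and Nrarp, a feedback inhibitor of Notch, one of -0.98 ± 0.26, with adjusted p = 0.064 and 0.093 over all genes. Hes1, a repressor of neuronal differentiation, measured 113 ± 23.5 CPM with DBZ and 156 ± 13.5 CPM with vehicle (SD, adjusted p = 0.17). Hes5 was scarcely detected, at 0.11 ± 0.13 CPM with DBZ and 0.51 ± 0.35 CPM with vehicle (SD). The list test gave adjusted p = 8.3e-07, and adjusted p = 0.024 with an estimated correlation. Single libraries decided some of these calls over all genes: Hey1 passed without DBZ replicate 2 (adjusted p = 0.021), Nrarp without DBZ replicate 4 (0.041) and Hes1 without DBZ replicate 3 (0.025).

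Among the receptors and ligands, the receptor gene Notch1 was lower. Notch1 (chromosome 2, 26457903 to 26516663) fell 1.51-fold, from 120 ± 10.7 to 79.8 ± 5.91 CPM (SD), with adjusted p = 0.0040, and was the only one of 19 tested receptors, ligands and modulators called over all genes. With p-values adjusted over the list alone, Notch1 was lower and 2 genes, Numbl and Jag2, were higher; without DBZ replicate 2 Numbl also passed over all genes (0.019). The ligands Dll1 and Dll4 had log2 fold changes of 0.69 ± 0.36 and 0.66 ± 0.26 (SE), with adjusted p = 0.46 and 0.29. The list as a whole did not pass (adjusted p = 0.22), but it did without DBZ replicate 2 (adjusted p = 0.038). None of the 7 gamma-secretase subunits passed, over all genes or over the list alone. Psen1, a catalytic subunit, measured 88.4 ± 10.8 CPM with DBZ and 86.9 ± 4.74 CPM with vehicle (SD), and the subunit list had adjusted p = 0.064, but 0.045 without DBZ replicate 1 and 0.038 without DBZ replicate 2, 0.044 with library size alone as the scaling, 0.032 with no filter on low counts and 0.045 after thinning to equal depth, with higher values under DBZ in each.

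**Figure D2:**
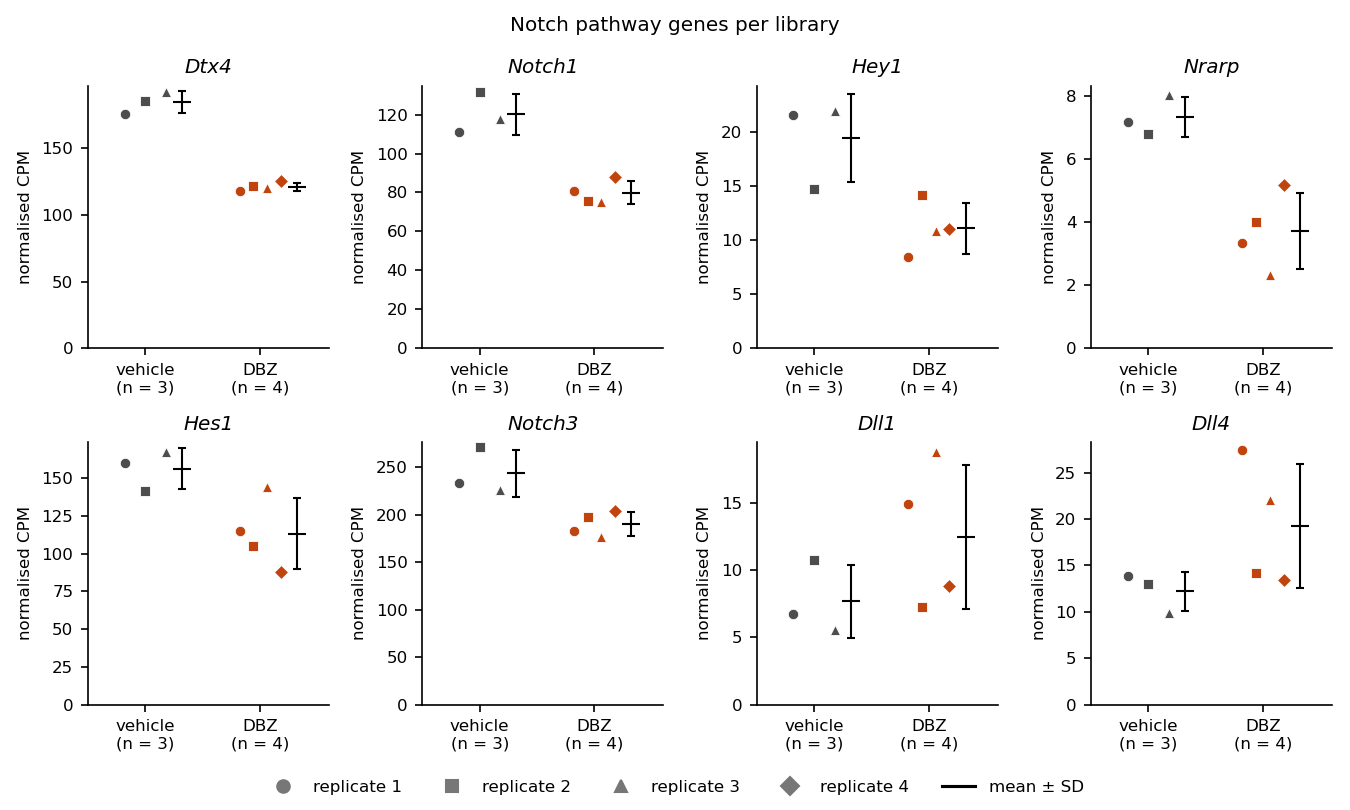
Normalised CPM of 8 Notch pathway genes in each library (symbols, replicate numbers as in the key), with the mean and SD of the 3 vehicle and 4 DBZ libraries beside them. Dtx4 and Notch1 separate the groups with little spread, while the DBZ libraries of Dll1 and Dll4 scatter around higher means without passing the test.

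Retinal progenitor genes were lower as a list with the preset correlation (adjusted p = 1.7e-10), but not with an estimated correlation (adjusted p = 0.090 with an estimated correlation). Of 19 tested, 3 were lower over all genes (Sfrp2, Hmga2 and Fzd5) and none was higher, and 8 were lower adjusted over the list alone. Sfrp2, a secreted Wnt modulator of the early retina (chromosome 3, 83766321 to 83774316), fell 2.90-fold, from 1485 ± 155 to 513 ± 159 CPM (SD). Hmga2, a chromatin protein of progenitor cells, fell 1.49-fold and Fzd5, a Wnt receptor, fell 1.37-fold. Ccnd1, the cyclin that drives G1 in retinal progenitors, measured 214 ± 71.5 CPM with DBZ and 425 ± 52.1 CPM with vehicle (SD), a log2 fold change of -0.99 ± 0.23 (SE) with adjusted p = 0.093. Without DBZ replicate 2 Ccnd1 passed (adjusted p = 0.00042), without DBZ replicate 3 the call of Sfrp2 ended (adjusted p = 0.054), and the call of Fzd5 ended without DBZ replicate 1 (0.098) or vehicle replicate 1, 2 or 3 (0.051, 0.12 and 0.11).

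Neurog2 and Atoh7 differed between the DBZ libraries. Neurog2 and Atoh7, basic helix-loop-helix factors of cells entering neurogenesis, were close to absent in DBZ replicates 1, 3 and 4 and present in DBZ replicate 2 and all vehicle libraries. Neurog2 (chromosome 3, 127633135 to 127635631) measured 0.61, 6.65, 0.88 and 0.83 CPM in DBZ replicates 1 to 4 and 6.89, 16.2 and 16.4 CPM in vehicle replicates 1 to 3. Atoh7 (chromosome 10, 63099651 to 63101279) measured 1.61, 10.7, 0.52 and 0.069 CPM in the DBZ libraries and 4.54, 15.4 and 16.9 CPM in the vehicle libraries. With that spread neither passed (adjusted p = 0.34 and 0.68), whereas without DBZ replicate 2 Neurog2 was called, with a log2 fold change of -4.10 and adjusted p = 0.00050, and so was Neurod1 (adjusted p = 0.030). Ascl1, another proneural factor, did not follow this pattern: it measured 6.08, 1.80, 5.35 and 2.75 CPM in DBZ replicates 1 to 4, with means of 4.00 ± 2.05 CPM with DBZ and 2.86 ± 0.82 CPM with vehicle (SD, adjusted p = 0.70). None of the 16 tested neurogenic precursor genes was called, over all genes or over the list alone, and the list test gave adjusted p = 0.34.

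Markers of photoreceptor precursors had higher fitted means with DBZ. All 9 tested had positive fold changes, with a median log2 fold change of 0.60; none passed over all genes, and Rxrg and Crx were higher adjusted over the list alone. Rxrg, a nuclear receptor of cone photoreceptors, measured 147 ± 37.0 CPM with DBZ and 75.6 ± 7.73 CPM with vehicle (SD), and Crx, a photoreceptor transcription factor, 17.3 ± 6.40 and 6.69 ± 2.33 CPM. Otx2, which acts upstream of Crx and is also expressed in pigment epithelium, measured 108 ± 29.4 and 79.4 ± 15.0 CPM. By library, Rxrg (166, 99.8, 185 and 138 CPM in DBZ replicates 1 to 4) and Otx2 (134, 75.2, 132 and 91.6 CPM) had the same lowest DBZ library as the pigment epithelium gene Pmel (1441, 595, 1490 and 1120 CPM), while Crx was highest there (12.9, 26.7, 13.6 and 16.0 CPM). The list test gave adjusted p = 2.1e-05, but adjusted p = 0.090 with an estimated correlation. Without DBZ replicate 2, Rxrg (adjusted p = 0.00099) and Crx (0.043) were called over all genes.

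**Figure D3:**
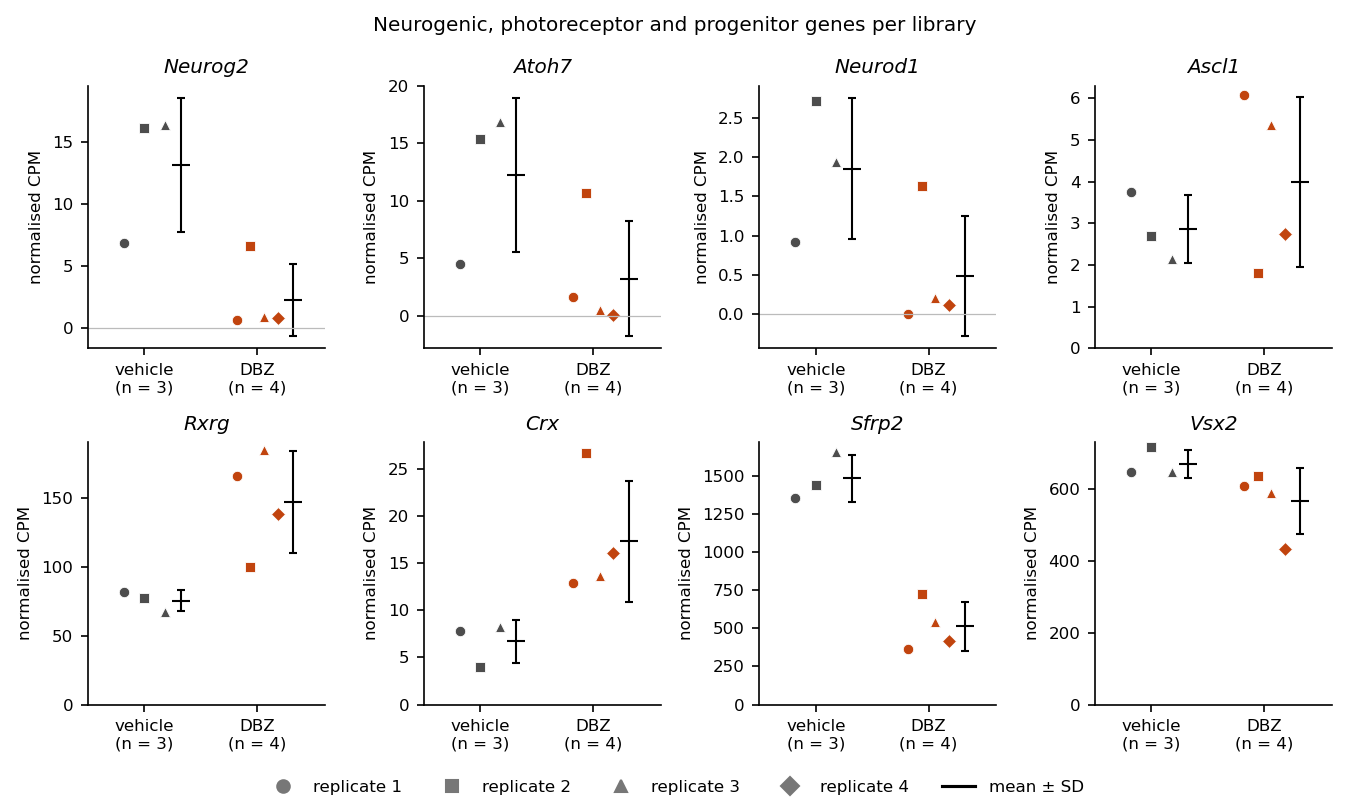
Normalised CPM of 8 neurogenic, photoreceptor and progenitor genes in each library (symbols, replicate numbers as in the key), with the mean and SD of the 3 vehicle and 4 DBZ libraries beside them. DBZ replicate 2 holds 6.65 CPM of Neurog2 and 10.7 CPM of Atoh7, where the other DBZ libraries hold at most 0.88 and 1.61 CPM.

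Markers of differentiated retinal neurons gave no calls over all genes. None of the 18 tested retinal ganglion cell markers and none of the 19 pan-neuronal genes passed over all genes (list tests, adjusted p = 0.091 and 0.28). When adjusted over the list alone, Robo2, an axon guidance receptor, was higher (36.8 ± 7.54 against 21.4 ± 4.84 CPM, SD), and no pan-neuronal gene was called. Without DBZ replicate 2 Robo2 passed over all genes (adjusted p = 0.0097). The ganglion cell list passed without DBZ replicate 2 (adjusted p = 0.030) and without vehicle replicate 2 (0.043), and with the stricter filter on low counts (0.023). Pou4f2, a ganglion cell factor, had at most 18 counts in any library and was too low to be tested, and Isl1 measured 5.52 ± 3.44 CPM with DBZ and 5.21 ± 0.44 CPM with vehicle (SD). None of the 8 horizontal and amacrine cell markers passed (list adjusted p = 0.090), but the list did in the downward direction without DBZ replicate 2 (0.0087), DBZ replicate 4 (0.044), vehicle replicate 1 (0.047) or vehicle replicate 3 (0.034), and with library size alone as the scaling (0.047). Foxn4, a factor of horizontal and amacrine cell fate, measured 7.91 ± 5.11 CPM with DBZ and 29.8 ± 5.70 CPM with vehicle (SD, adjusted p = 0.16), and it was called without DBZ replicate 2 (0.0063). Of 10 glial genes and 12 genes of the ciliary margin and optic stalk none passed over all genes (list adjusted p = 0.099 and 0.94). Of these, only Wfdc1 was lower when adjusted over the list alone, and without DBZ replicate 2 it passed over all genes (0.0060).

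The share of lens transcripts varied between the cultures far more than between the groups. Lens markers made up 0.246%, 0.585%, 0.0404% and 1.20% of gene counts in DBZ replicates 1 to 4 and 0.822%, 0.0519% and 1.62% in vehicle replicates 1 to 3, a 40.2-fold range. The group means were 0.518% ± 0.508 (SD, n = 4) and 0.833% ± 0.786 (SD, n = 3), with an exact two-sided permutation p of 0.49 over 35 splits, which can give no p below 0.0286. The difference was -0.314 percentage points, and it turned to 0.0812 without vehicle replicate 3. Cryaa, the most abundant lens crystallin gene, measured 2015 ± 1917 CPM with DBZ and 3636 ± 3344 CPM with vehicle (SD). None of 22 lens markers was called, and the lens list had adjusted p = 0.31, although it passed in the downward direction without DBZ replicate 4 (0.0024) and without vehicle replicate 2 (8.3e-08), and in the upward direction when DBZ replicate 3 and vehicle replicate 3 were both left out (3.3e-05). These calls used the preset correlation. With the estimated correlation of 0.87, the lens list had adjusted p = 0.88 (camera) on all 7 libraries. Erythroid genes made up 0.0306% ± 0.0167 of counts with DBZ and 0.0418% ± 0.0274 with vehicle (exact permutation p = 0.49). None of the 10 erythroid genes passed over all genes, 1 (Hbb-bt) was lower adjusted over the list alone, and the list had adjusted p = 0.064, with a call in the downward direction without DBZ replicate 2 (0.0062) and without vehicle replicate 1 (4.7e-07), and on all 7 libraries with library size alone as the scaling (0.030), no filter on low counts (0.012) or the lens covariate (0.038). With the estimated correlation of 0.74, the erythroid list had adjusted p = 0.53 (camera) on all 7 libraries.

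Markers of tissues around the retina had higher fitted means with DBZ, but no single gene passed over all genes. The medians of the log2 fold changes were 1.23 for 13 endothelial markers, 0.95 for 12 periocular mesenchyme markers, 0.54 for 13 microglia and macrophage markers and 0.43 for 15 genes of the retinal pigment epithelium. Plvap, an endothelial protein, measured 5.59 ± 1.93 CPM with DBZ and 1.79 ± 0.69 CPM with vehicle (SD), Lum, a matrix proteoglycan of mesenchyme, 22.0 ± 9.76 and 7.46 ± 1.75 CPM, and Pmel, a melanosome protein, 1162 ± 412 and 702 ± 179 CPM. DBZ replicate 2 lay near the vehicle libraries for several of them, with 8.80 CPM of Lum (vehicle 9.20, 7.48 and 5.69), 595 CPM of Pmel (vehicle 855, 746 and 506) and 20.9 CPM of C1qb, a microglial complement gene (vehicle 24.8, 24.6 and 28.7). Counts adjusted over the list alone were higher: 3 endothelial genes (Plvap, Emcn and Sox18) and 3 mesenchyme genes (Dcn, Prrx1 and Lum), and none of the microglia or pigment genes. Without DBZ replicate 2, Plvap, Emcn, Dcn, Lum and Pmel passed over all genes (adjusted p = 0.012, 0.0092, 0.0088, 0.0011 and 0.028). The list tests gave adjusted p = 5.7e-08 for endothelial, 1.0e-05 for mesenchyme, 0.0014 for microglia and 0.00052 for pigment epithelium genes. With an estimated correlation none of the 4 lists passed (adjusted p = 0.28, 0.33, 0.38 and 0.44), where members of each list varied together between cultures. The microglia call ended without DBZ replicate 4 (median 0.22, adjusted p = 0.073) and the pigment epithelium call when DBZ replicate 3 and vehicle replicate 3 were both left out (0.20). With the replicate block the microglia median was 0.18 and the endothelial median 0.79, and without vehicle replicate 1 the pigment epithelium median was 0.65. Mitf, a master regulator of pigment cells, measured 266 ± 18.5 CPM with DBZ and 262 ± 24.0 CPM with vehicle (SD, adjusted p = 0.96). Of 5 neural crest and 5 surface ectoderm genes none passed (list adjusted p = 0.15 and 0.94); the surface ectoderm median was 0.10 while its test pointed downward, and the median lay below 0 without DBZ replicate 2 or 3 (-0.06 and -0.03) or vehicle replicate 2 or 3 (-0.06 and -0.04).

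Metabolic and stress genes changed in small numbers. Of 14 integrated stress response genes 3 were called as lower over all genes and none as higher, and 8 were lower adjusted over the list alone. The 3 were Mthfd2 (1.90-fold), Psat1 (1.84-fold) and Shmt2 (1.35-fold), enzymes of serine and mitochondrial one-carbon metabolism. The list test gave adjusted p = 2.9e-07, and adjusted p = 0.063 with an estimated correlation. Hspa1a and Hspa1b, inducible heat shock proteins, were 1.95-fold and 1.93-fold higher and were the only 2 of 14 immediate early and heat shock genes called, over all genes or over the list alone; they are near-identical neighbours on chromosome 17, so their reads cannot be fully told apart. Pdk1, a kinase that inhibits pyruvate dehydrogenase, was 1.42-fold higher and the only one of 15 hypoxia and glycolysis genes called over all genes (adjusted over the list alone, 3 higher and 2 lower). Lgr5, a Wnt target, was 1.85-fold lower and the only one of 9 Wnt targets called (adjusted over the list alone, 1 higher and 2 lower). No Hedgehog pathway gene (10 tested) or p53 target (16 tested) passed over all genes. In counts adjusted over the list alone, 1 Hedgehog gene was higher and 2 were lower, and 1 p53 target, Aen, was lower; Aen passed over all genes without DBZ replicate 2 (0.041) or 4 (0.046). The list tests gave adjusted p = 0.099 for the immediate early, 0.37 for the hypoxia, 0.33 for the Wnt, 0.11 for the Hedgehog and 0.94 for the p53 list; the Wnt and p53 medians (0.07 and 0.03) lay above 0 while their tests pointed downward. The signs of these medians were not stable: the Wnt median was -0.27 without DBZ replicate 4 and with the replicate block, -0.05 without vehicle replicate 1, -0.06 without a filter and -0.17 with the stricter filter, and the p53 median was -0.02 without DBZ replicate 3 and -0.07 without DBZ replicate 3 and vehicle replicate 3 together. The Hedgehog list passed in the downward direction without vehicle replicate 3 (0.034), and the immediate early list in the upward direction without vehicle replicate 2 (0.027) or 3 (0.0024), without DBZ replicate 3 and vehicle replicate 3 together (0.017) and with the stricter filter (0.042); its direction turned without vehicle replicate 1 (median -0.13, adjusted p = 0.58). The calls of Hspa1a, Hspa1b, Pdk1, Lgr5 and Shmt2 each ended without DBZ replicate 1 (adjusted p = 0.073, 0.079, 0.067, 0.089 and 0.055), without vehicle replicate 1 (0.10, 0.11, 0.075, 0.14 and 0.099) and without vehicle replicate 3 (0.11, 0.12, 0.14, 0.080 and 0.066). Those of Pdk1, Lgr5 and Shmt2 also ended without vehicle replicate 2 (0.090, 0.066 and 0.052).

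Outside these lists, the called genes with a mean of at least 5 CPM that rose most were of mixed function. Doc2b, a calcium sensor of vesicle release (chromosome 11, 75768966 to 75796049), rose 2.99-fold, from 17.8 ± 3.76 to 53.1 ± 9.97 CPM (SD), and Ap3b2, a neuronal adaptor complex subunit, rose 2.62-fold. Myl9, a myosin light chain, rose 2.29-fold, Filip1l, a filamin-interacting protein, 2.24-fold and Wnk4, a kinase of ion transport, 2.17-fold. Tfec, a transcription factor related to Mitf, rose 1.82-fold and Mfap4, a microfibril protein, 1.82-fold. Above the same level of 5 CPM, the genes that fell most after Sfrp2 included Optc, a secreted proteoglycan of the eye (2.85-fold), Etv5, an ETS factor induced by fibroblast growth factor signalling (2.71-fold), and E2f7, an atypical E2F repressor (2.64-fold). Adgrg1, an adhesion G protein-coupled receptor, fell 2.43-fold, Nsl1, a kinetochore protein, 2.28-fold, Fst, an activin antagonist, 2.21-fold and Sapcd2, a regulator of spindle orientation, 2.20-fold. Gcgr, Dact2 and Htra1 completed the 8 largest rises above that level at 2.43-fold, 2.23-fold and 2.15-fold. Of these 18 genes, Doc2b, Myl9, Filip1l, Wnk4, Tfec, Mfap4, E2f7, Nsl1 and Sapcd2 stayed called whichever library was left out. Sfrp2 aside, the calls of the others ended as follows. Without vehicle replicate 3 the adjusted p was 0.070 for Ap3b2, 0.066 for Adgrg1, 0.087 for Gcgr, 0.11 for Dact2, 0.15 for Fst, 0.18 for Etv5 and 0.19 for Htra1. Without vehicle replicate 2 it was 0.066 for Adgrg1, 0.076 for Optc, 0.058 for Gcgr, 0.10 for Dact2, 0.068 for Fst, 0.14 for Etv5 and 0.19 for Htra1. Without vehicle replicate 1 it was 0.059 for Ap3b2, 0.058 for Gcgr, 0.11 for Fst, 0.12 for Etv5 and 0.099 for Htra1. Without DBZ replicate 1 it was 0.058 for Adgrg1, 0.061 for Optc, 0.052 for Gcgr, 0.080 for Dact2, 0.12 for Fst, 0.12 for Etv5 and 0.16 for Htra1. Without DBZ replicate 3 it was 0.070 for Adgrg1, 0.053 for Gcgr, 0.055 for Dact2, 0.065 for Etv5 and 0.11 for Htra1. Without DBZ replicate 4 it was 0.060 for Fst and 0.071 for Htra1, and without DBZ replicate 2 it was 0.070 for Etv5. Among the rises, DBZ replicate 2 was the lowest DBZ library for Mfap4 (170 CPM), Myl9 (18.8), Ap3b2 (18.0), Dact2 (10.9) and Htra1 (7.17), as for Lum and Pmel. It was the highest for Filip1l, Wnk4 and Gcgr, and neither for Doc2b and Tfec. Whether surrounding tissue contributed to these rises was not tested.

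**Figure D4:**
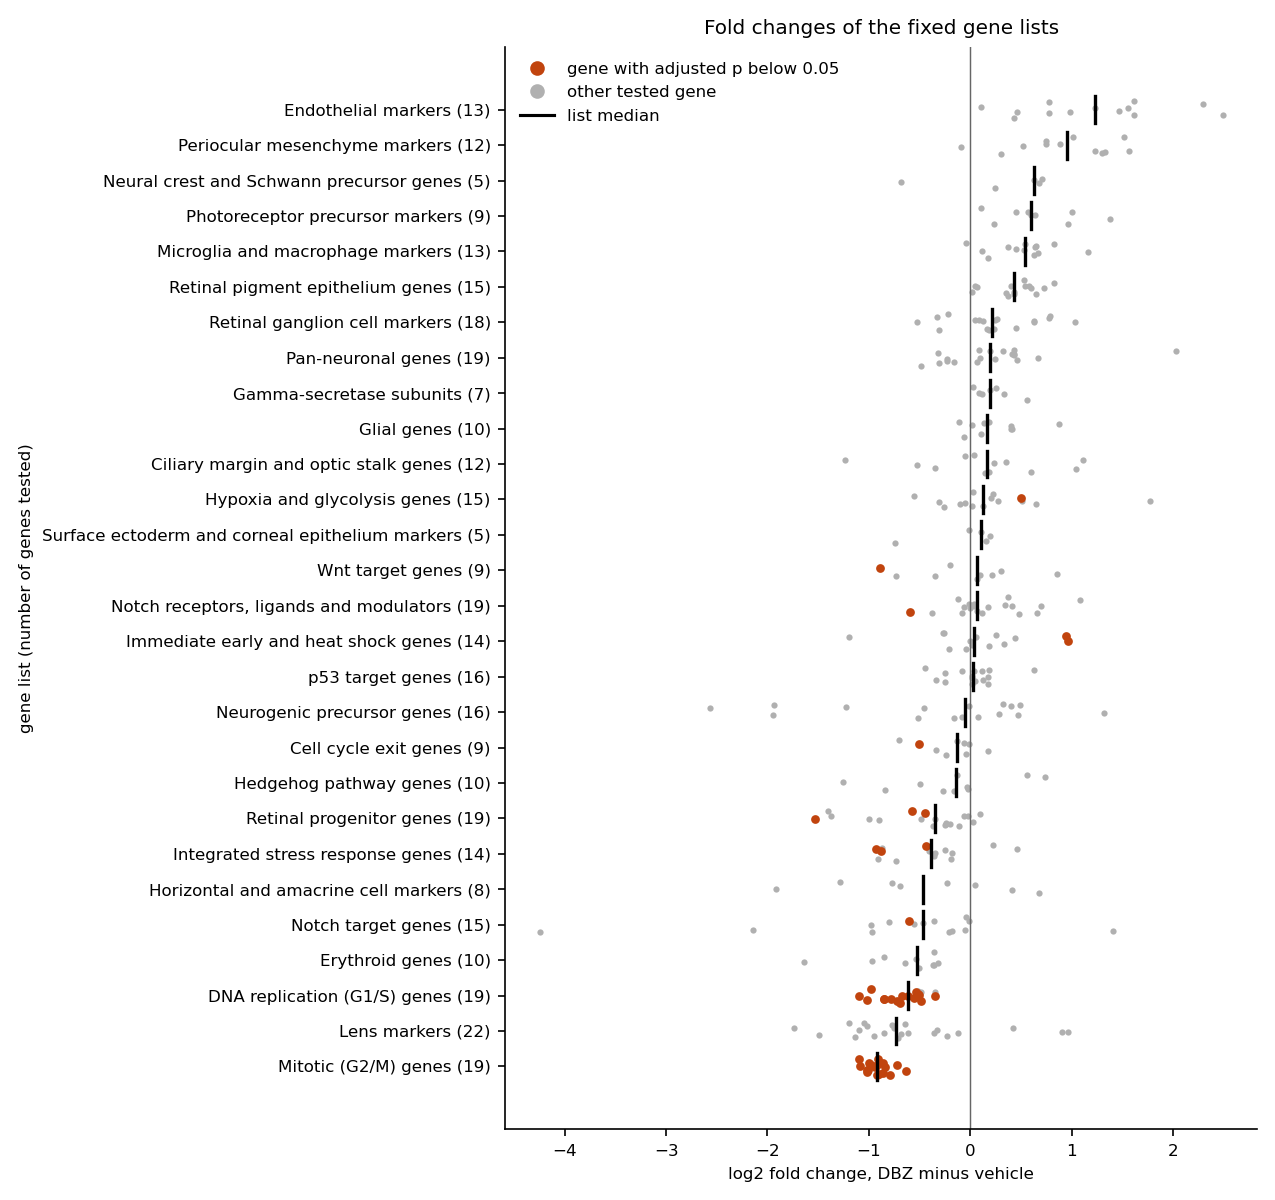
Log2 fold changes (DBZ minus vehicle, horizontal axis) of the tested members of 28 gene lists fixed in advance, 1 list per line with its number of tested genes in brackets. Each point is a gene, in orange-red where it passed the test over all genes, and the vertical bar is the median of the list. The mitotic and DNA replication lists lie wholly below 0 with nearly every gene called, while the endothelial and mesenchyme lists have medians of 1.23 and 0.95 with no gene called.

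In total 11 of the 28 gene lists passed with the preset correlation and 3 (mitotic, DNA replication and Notch target genes) with an estimated correlation. A further test (fry) asked whether genes of a list move on balance in a single direction, without comparison with other genes. With it 8 lists passed. These were mitotic, DNA replication, Notch target, integrated stress response, photoreceptor precursor, retinal progenitor, Wnt target and cell cycle exit genes (adjusted p = 0.00096, 0.0017, 0.0025, 0.0025, 0.021, 0.021, 0.021 and 0.034). The endothelial, mesenchyme, microglia and pigment epithelium lists did not pass (0.21, 0.25, 0.29 and 0.31).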

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

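The test of low counts and that of a vehicle library under a DBZ label were chosen after the result was seen. A value was singled out when the highest or lowest of the 4 DBZ libraries stood apart by more than Dixon's 95% limit, which chance exceeds in about 1 of 20 groups. Of 99 genes in the text 11 did so, and of all tested genes 6.09%, so chance alone gives 4.95 of 99 and the rate of all tested genes 6.03, a large part of the 11. In 7 of the 11 the library standing apart was DBZ replicate 2, against 298 of 1224 over all tested genes. Over all tested genes it was more often DBZ replicate 3 (366) or DBZ replicate 4 (409). DBZ replicate 3 correlated with the other libraries at 0.948 to 0.964 (log CPM), against 0.957 to 0.974 for DBZ replicate 2. It also had the fewest genes with any count (22191). DBZ replicate 2 was therefore not the most distant library as a whole.

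DBZ replicate 2 was the highest DBZ library for Neurog2 (6.65 CPM, the others 0.61 to 0.88), Atoh7 (10.7 CPM, the others 0.069 to 1.61), Neurod1 (1.63 CPM, the others 0 to 0.21) and Ccnd1 (320 CPM, the others 165 to 185). It was also highest for Filip1l (156 CPM, the others 108 to 113), Adgrg1 (23.4 CPM, the others 12.0 to 13.8) and Nkd1 (121 CPM, the others at least 93.1). Counting error does not account for the proneural genes: the lower 95% Poisson bounds of DBZ replicate 2 for Neurog2 and Atoh7 were at least 4.65 times the highest upper bounds of the other DBZ libraries. A vehicle library under a DBZ label is argued against by the 35 cell cycle genes called without DBZ replicate 2. Over these genes it lay at 0.818 of the way from the vehicle mean to the mean of the other DBZ libraries. Dtx4 and Notch1, at 122 and 75.4 CPM, also lay within the range of the DBZ group. Both were called with DBZ replicate 2 counted as DBZ, so they do not test its label. A weaker drug exposure of this culture stays open: over 769 genes called without it, DBZ replicate 2 lay at 0.373 of that way. DBZ replicates 1, 3 and 4 lay at 1.06, 0.948 and 0.793 over genes called without each. Those sets held 179, 292 and 339 genes and were called with DBZ replicate 2 in the group. The contrast with 0.373 is therefore partly built in and is weak support for a weaker exposure. Over the called Notch target genes, only 1 to 3 per library, DBZ replicates 1 to 4 lay at 1.09, 0.281, 0.602 and 0.364. These few genes did not set DBZ replicate 2 apart from DBZ replicate 4, and Heyl had no count in DBZ replicate 2. A difference in stage or dissection between cultures was not tested and stays open too: DBZ replicate 2 was also the lowest DBZ library for Lum, Pmel and C1qb, markers of tissues around the retina and of microglia, at 8.80, 595 and 20.9 CPM.

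For the remaining genes, DBZ replicate 3 was the highest DBZ library for Fst (5.43 CPM, the others 3.31 to 3.45) and for Pdk1 (59.9 CPM, the others 49.3 to 50.8). DBZ replicate 4 was the lowest for Shmt2 (70.3 CPM, the others 79.9 to 81.5). DBZ replicate 4 was the highest for Heyl, at 0.918 CPM against at most 0.070 CPM in the others.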

How the results depend on the processing

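Thinning, removal of GC and length trends, leaving out 2 libraries together and the Reactome sets were chosen after the data were seen. All 386 called genes kept their direction under every setting that tested them. Their groups do not overlap, so leaving out libraries could hardly turn it, and this is weak support. The number called stayed within 1.5 times of 386 with RLE, library size alone, limma-voom, robust estimation off, lens markers removed, the lens covariate, the stricter filter, thinning, GC and length trends removed, and the replicate block. It was 684 without a filter (201 higher, 483 lower), 882 with DESeq2 (333 higher, 549 lower), 151 without DBZ replicate 3 and vehicle replicate 3 (10 higher, 141 lower) and 27 against a log2 change of 0.5, which asks for larger changes; for the other settings the cause was not tested. Genes higher with DBZ numbered 104 with the stricter filter and 115 with GC and length trends removed. Without single libraries the count ran from 168 to 769, higher genes from 11 to 299 and lower genes from 156 to 470. Fewer samples lower the power of these fits. Over the 769 genes called without DBZ replicate 2, that library lay nearer the vehicle mean (0.373), but over the called cell cycle genes it did not (0.818). The first value covers the very genes that make up the rise, so it does not explain the rise. Of 38 cell cycle genes, 26 to 38 were called and lower under each setting except the test against a log2 change of 0.5, which kept 8. Called lists numbered 11 to 16 with the preset correlation and 3 with an estimated correlation, which allows for members varying together. Members varying together do not account for all of this drop in strength. The Notch target list had an estimated correlation of -0.031, and its adjusted p (camera) still rose from 8.3e-07 to 0.024. The lens share difference ran from -0.705 to 0.0812 percentage points without single libraries, positive only without vehicle replicate 3.

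The replicate numbers gave no clear sign of pairing: same-numbered deviations correlated at 0.068, 0.032 and -0.0024. DBZ replicates 1 and 2 correlated best with the vehicle library of their own number, but DBZ replicate 3 did not. No vehicle library correlated best with the DBZ library of its own number. Correlations this weak cannot exclude a shared litter or culture day. With the replicate block on replicates 1 to 3, 294 genes were called (47 higher, 247 lower), against 339 from the same 6 libraries without the block, and the horizontal and amacrine and the lens lists passed in the downward direction with the block (adjusted p = 0.0038 and 0.033) and without it (0.044 and 0.0024).

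Of 49 called genes in the text, 24 stayed called under all 20 settings that gave values per gene. Of 975 gene and setting pairs, 107 lost the call. None changed direction, which groups that do not overlap all but fix in advance. Of the uncalled genes, 101 of 981 pairs gained a call and 11 changed direction. Without single libraries Mitf ran from a log2 fold change of -0.026 to 0.10, Cryaa from -1.62 to 0.018, Psen1 from -0.064 to 0.071 and Isl1 from -0.42 to 0.32. Without DBZ replicate 3 and vehicle replicate 3 together Mitf was -0.039 and Cryaa 0.41, with the replicate block Psen1 was -0.063, and with limma-voom Isl1 was -0.11. With 4 and 3 libraries, 22.4% of simulated changes of 0.5 (log2) were recovered, so many of that size will be missed. After thinning to the smallest total, 383 of 18091 tested genes were called, and 351 of these were among the 386.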

Other observations

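The tests of library scaling, progenitor share, lens tissue, depth, and GC content with length on the cell cycle genes, of the Reactome sets and of ERK genes were chosen after the result was seen, although the fit with the lens covariate itself was set out before. Some genes of lipid supply, in none of the fixed lists and chosen after their values were seen, were lower with DBZ. Of 22 tested genes in the Reactome set of cholesterol biosynthesis 7 were called as lower and none as higher, with a median log2 fold change of -0.36. The set had adjusted p = 2.5e-12 among 867 sets with the preset correlation but adjusted p = 0.12 with an estimated correlation, with which 0 of the 867 sets passed (222 lower and 39 higher with the preset correlation). Ldlr, the receptor for low-density lipoprotein, fell from 75.4 ± 3.53 to 42.7 ± 2.07 CPM (SD, n = 3 and n = 4; edgeR adjusted p = 0.00041). Scd1, a fatty acid desaturase, fell 2.19-fold, from 56.2 ± 4.68 to 25.7 ± 1.42 CPM. Hmgcs1 and Hmgcr, enzymes early in sterol synthesis, fell 1.51-fold and 1.47-fold, Sqle, squalene epoxidase, 1.35-fold and Insig1, a sterol sensor protein, 1.40-fold. Ldlr and Scd1 stayed called whichever library was left out, while calls ended for Hmgcs1, Hmgcr and Sqle without vehicle replicate 3 (adjusted p = 0.053, 0.060 and 0.098), for Hmgcr and Sqle without DBZ replicate 1 (0.052 and 0.073), for Sqle without vehicle replicate 2 (0.069) and for Insig1 without vehicle replicate 1 (0.062).

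Heyl, a Notch effector chosen after its values were seen, was close to absent in 3 of the 4 DBZ libraries. It measured 0.070, 0, 0 and 0.92 CPM in DBZ replicates 1 to 4 and 2.31, 6.72 and 5.10 CPM in vehicle replicates 1 to 3, but did not pass over all genes (edgeR adjusted p = 0.23), except without DBZ replicate 4 (0.0015; up to 0.52 without other single libraries).

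Splits of the 7 libraries into 4 and 3 gave 35 groupings. For the 386 genes changed, 1 of 35, the real one, gave as many, and the highest other gave 338. A share of 1 of 35 is the lowest this number of splits can give, so chance is argued against but not excluded. The same holds for the 318 lower genes (1 of 35, highest other 205). For the 68 higher genes chance is not argued against, since 2 of 35 splits gave as many and the highest other gave 133. Nor is it for the 11 gene lists, since 7 of 35 gave as many and the highest other gave 17. The split with 338 genes, 133 higher and 205 lower groups DBZ replicate 2 with the 3 vehicle libraries.

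The fall of the DNA replication and mitotic genes was set against technical explanations. Library scaling is argued against, because a scaling factor moves all genes of a library alike, while the median of the 38 genes differed from that of all tested genes by a log2 difference of -0.86. Depth, lens tissue and GC content with length are argued against as the whole cause, because 35, 34 and 37 of the 38 genes stayed called and lower after thinning, with the lens covariate and with trends removed. A smaller share of progenitor cells stays open: the 38 genes differed from the 19 tested genes of the fixed progenitor list by a log2 difference of -0.22 (exact two-sided permutation p = 0.0857), and 5 of the 19, of which only Sfrp2 was called, had log2 fold changes as low as the median of the 38. Against 9 transcription factors of that list the log2 difference was -0.62 (exact two-sided permutation p = 0.0286, the lowest that 35 splits can give). These 9 were Vsx2, Rax, Pax6, Lhx2, Six3, Six6, Sox2, Meis1 and Meis2, with a mean log2 change of -0.18. None of the 9 was called, but they leave out the called genes of the list, so they do not settle the question.

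Genes induced by ERK signalling in negative feedback or as its targets appeared among the lower calls, and a wider list was then tested as a hypothesis. Etv4, an ETS factor, fell 3.07-fold (edgeR adjusted p = 0.0052) and Spry2, an inhibitor of receptor tyrosine kinase signalling, 1.83-fold (0.0088, but 0.058 without vehicle replicate 3). Among 9 related genes that had not drawn attention all 9 had lower fitted means, with a median log2 fold change of -0.38 and none called (Dusp6, -0.53 ± 0.14 (SE), adjusted p = 0.099). As a set they passed with an estimated correlation (camera p = 0.044, not adjusted). The fixed list of immediate early and heat shock genes, not part of this test, did not fall. Of its 14 genes 6 had lower fitted means, and its median log2 fold change was 0.04. Lower ERK signalling with DBZ may be a candidate explanation, but the margin is narrow. A change in cell composition was not excluded.

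Xist, the X-inactivation transcript, was present at 1247 to 2597 CPM in all 7 libraries, together with 0.78 to 1.35 CPM summed over 4 Y-linked genes.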
